A study of Caenorhabditis elegans with 80 samples.

How the data were processed

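Whole Caenorhabditis elegans at the middle of the L4 stage, the last larval stage, were exposed to acrylamide, cadmium or mercury in an axenic liquid medium (CeHR, a culture medium without bacteria). Polyadenylated RNA was amplified to biotin-labelled cRNA and read on 80 expression arrays, 1 array per sample. The deposited values were intensity, that is MAS5 signal per probe set on a linear scale, and the authors had scaled each array to a shared trimmed mean. The 2% trimmed mean lay between 493.5 and 497.4 in 79 of the 80 arrays and was 213.2 in replicate 1 of the acrylamide control at 0 h. No version of MAS5 and no scaling target was stated.

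Of 22625 probe sets, 77 array controls were left out. Of the remaining 22548, 20766 matched 1 gene symbol, 887 matched several and 895 matched none. Median signal ran from 80.32 (the array at 213.2 above, next 152.7) to 282.2, a ratio of 3.51. That array alone took it over the preset limit of 2, so all were centred on a median of 202.9. A pseudocount of 51, the 20th percentile of all signals, was added before taking log2. Folds of genes dim in controls depend on it: without it hsp-16.41 at 8 h of high cadmium and mercury changed by 6.27 and 8.17 instead of 5.41 and 6.4. A probe set was tested where at least 3 arrays of the series exceeded a signal of 131, the 40th percentile, without regard to group. This left 16533 probe sets for acrylamide, 16214 for cadmium and 15874 for mercury, and 17840 for fits over all arrays. The share of probe sets above that signal ran from 38.1% to 75.94% between arrays. Genome coordinates were not used here.

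Groups followed the sample titles: chemical, dose, exposure time and replicate. Each series was fitted with limma (version 3.58.1 in R 4.3.3), 1 mean per group, with moderated variances that follow the mean signal (residual degrees of freedom 18, 17 and 18). Each dose was compared with the control of the same series and time. Further contrasts were the trend over control, low, mid and high dose in equal steps, the high-dose effect at 8 h less that at 4 h, and the control at 8 h less the control at 0 h. Differences between chemicals came from 1 fit of all 80 arrays (residual degrees of freedom 53), each chemical set against its own control. The p values were adjusted by the Benjamini-Hochberg method within each contrast, and a probe set was called at an adjusted p under 0.05. Calls at the high dose were compared between chemicals with a two-sided Fisher's exact test on probe sets tested in both series, adjusted over 12 overlaps.

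The gene level used 1 probe set per gene (17118 genes), that of the highest mean signal. A probe set whose suffix marks possible cross-hybridization was taken where a gene had no other, as for 3500 genes. Such genes named in the text include mtl-2, ftn-1, hsp-70, hsp-4, cdr-4, act-5, vit-4, vit-5, elo-5, puf-5 and the nlp genes. There were 35 gene lists, written from general knowledge before the data were examined. They covered metallothionein and cadmium response, zinc, iron, copper and heme handling, cytosolic heat shock proteins, the unfolded protein responses of the endoplasmic reticulum and of mitochondria, glutathione S-transferases, SKN-1 targets and glutathione synthesis, antioxidant enzymes, cytochromes P450, UDP-glucuronosyltransferases, short-chain dehydrogenases and ABC transporters. They also covered the hypoxia and hydrogen sulfide response, osmotic stress and glycerol, epidermal antimicrobial peptides, C-type lectins, lysozymes and saposin-like proteins, the intracellular pathogen response, proteasome subunits, cytosolic ribosomal proteins, DNA damage and apoptosis, and DNA replication and cell cycle. The remaining lists were fatty acid desaturases and elongases, lysosomal lipases and fasting response, vitellogenins, cuticle collagens, moulting, hedgehog-related proteins, pharyngeal prion-like abu proteins, sperm, oocyte and germline, intestine markers, body wall muscle markers, pharyngeal muscle markers and neuron markers. Some genes sit in several lists: gst-4, gst-12, gst-30 and ugt-13 are also SKN-1 list members, and mtl-2 is also an intestine marker. Of 293 members fixed by name, 19 had no probe set of their own, among them numr-1.

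Each list was tested with camera from limma at a preset correlation between genes of 0.01, adjusted over 210 tests at the high dose and 105 in the controls. Each test was repeated with the correlation estimated from the data (adjusted p given as with an estimated correlation, or when estimated). A count adjusted over the list alone (written over the list) stands beside each count of members called over all genes. The naming rule was fixed before the data were seen. It took per high-dose contrast up to 8 higher and 6 lower genes of largest change, with all exposed arrays on one side of all controls. It added up to 4 called members per called list, and mtl-1, mtl-2, cdr-1, numr-1, gst-4, gcs-1, hsp-16.2, hsp-16.41, hsp-70, hsp-4, hsp-6 and sod-3 (not all at 8 h of acrylamide and mercury). Genes named for the controls, for the effect at 8 h less that at 4 h and for differences between chemicals were chosen after their values were seen.

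Alternatives were quantile normalization, no pseudocount (signals under 3.04, the 1st percentile, were set to it), no filter on dim probe sets, replicate number as a block, a fit on only the compared groups, and leaving out each array in turn. For contrasts over more than a pair of groups, each replicate number was left out in turn. The authors' scaling without centring, the cadmium fits excluding 1 array, the gene lists under quantile normalization and the actin ratio as a covariate at 4 h were added after the data were seen. Splits of the same arrays into other groups were counted, all 10 for 3 against 3 and 100 random draws otherwise. A simulation held 200 changed probe sets per contrast. At the high dose 36% to 75% of 2-fold and 90% to 99% of 4-fold changes were recovered. Per contrast 2.1% to 11.1% of calls were false. Real data, mostly with more calls, may differ. Figures were drawn with matplotlib 3.10.9.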

Results

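Transcript levels were measured in whole L4 nematodes after exposure to acrylamide, a reactive industrial monomer, or to the toxic metals cadmium and mercury. Each chemical formed its own series with its own controls. Doses, called low, mid and high here, were 100, 500 and 1000 mg/L of acrylamide, 5, 20 and 50 mg/L of cadmium, and 5, 10 and 25 mg/L of mercury. Worms were collected after 4 h and 8 h of exposure together with unexposed controls, and a further control was taken at 0 h. The 80 arrays fell into 27 groups, with 27 arrays for acrylamide, 26 for cadmium and 27 for mercury. Every group held 3 arrays except the cadmium mid dose at 4 h, with n = 2. Signals correlated within a group between 0.793 and 0.983 (median 0.959). The labels do not say how far the replicates were grown apart, so the p values measure the spread between these samples, which may be partly technical. Errors below are standard errors (SE) of the log2 change, with n = 3 exposed and 3 control arrays unless stated.

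The first comparison asks what acrylamide did to transcripts within 4 h of the high dose. Lists of conjugation and glutathione genes were higher. Among 17 SKN-1 targets and glutathione synthesis genes, the regulon of the worm's main electrophile sensor, 12 rose and 0 fell (14 and 0 adjusted over the list alone). Their median log2 change was 2.00 (camera adjusted p = 1.24e-28, and adjusted p = 0.0106 with an estimated correlation). Of 40 glutathione S-transferases, 21 rose and 6 fell (25 and 7 over the list), with a median of 1.2 (adjusted p = 3.9e-19, and 0.0223 when estimated). The transferase genes gst-30, gsto-2, gst-12 and gst-31 rose 50.4-fold, 31.1-fold, 25.6-fold and 21.1-fold. For gst-30 the log2 change was 5.66 (SE 0.57, adjusted p = 1.9e-07). The nitrilase gene nit-1 rose 11.7-fold (SE 0.24, adjusted p = 2.5e-10). The gene of the rate-limiting enzyme of glutathione synthesis, gcs-1, rose 5.1-fold (SE 0.22, adjusted p = 6.3e-08), and gst-4, the usual SKN-1 reporter gene, rose 4.89-fold (SE 0.26, adjusted p = 1.1e-06).

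The list of UDP-glucuronosyltransferases, which couple sugar acids to foreign compounds, was also higher at 4 h of high acrylamide. Of 55 members 22 rose and 1 fell (25 and 1 over the list), with a median of 0.52 (adjusted p = 9.77e-13, and 0.0389 with an estimated correlation). The gene ugt-13 rose 23.2-fold (SE 0.32, adjusted p = 4.1e-10) and ugt-2 rose 5.86-fold. Among 41 cytochromes P450, 8 rose and 0 fell (11 and 1 over the list; adjusted p = 0.000146, but 0.0866 when estimated). Of these, cyp-34A9 rose 8.99-fold. Antioxidant enzymes gave 3 higher and 0 lower of 18 (6 and 1 over the list), led by the methionine sulfoxide reductase gene msra-1, 8.66-fold, and the peroxidase gene gpx-1, 3.22-fold (adjusted p = 0.0134, but 0.376 when estimated). The ferritin gene ftn-1 rose 28.8-fold (SE 0.38, adjusted p = 2.9e-09). It led the zinc, iron, copper and heme list, where 3 of 15 rose and 1 fell (3 and 1 over the list; adjusted p = 0.0193, but 0.181 when estimated). The genes clec-9, with a C-type lectin domain, and W06H8.2 rose 46.5-fold and 45.2-fold.

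The metallothionein genes went the other way at 4 h of high acrylamide. The transcript of mtl-1 fell 6.65-fold (log2 change -2.73, SE 0.37, adjusted p = 1.4e-05) and that of mtl-2 fell 5.94-fold (-2.57, SE 0.39, adjusted p = 6.7e-05). The largest decrease was that of rips-1, 25.9-fold (-4.69, SE 0.19, adjusted p = 3e-14). Of sulfide handling genes, the sulfide quinone oxidoreductase gene sqrd-1 was 9.71-fold lower and the cysteine synthase-like gene cysl-3 2.98-fold lower. The list of 8 hypoxia and hydrogen sulfide genes held 0 higher and 3 lower (0 and 3 over the list; adjusted p = 0.000812, but 0.21 with an estimated correlation). The astacin protease gene nas-27 fell 14.6-fold and the acyl-CoA oxidase gene acox-1.2 fell 8.60-fold. Markers of intestine (median -0.23, adjusted p = 0.0213) and of body wall muscle (median -0.43, adjusted p = 0.00359) were lower, with adjusted p = 0.554 and 0.426 when estimated. Of 11 intestine markers 0 rose and 3 fell (1 and 5 over the list), among them the microvillar actin gene act-5, 2.80-fold. Of 10 muscle markers 0 rose and 1 fell (0 and 2 over the list). Heat shock genes did not pass the threshold, with hsp-16.2 at 0.87 (adjusted p = 0.27), hsp-16.41 at 0.76 (0.58) and hsp-70 at 0.75 (0.077). The call for hsp-70 depended on the setting: it passed under the authors' scaling (adjusted p = 0.027) and without replicate 1 of the high dose (adjusted p = 0.021). Neither cdr-1 (0.79, adjusted p = 0.25), hsp-6 (-0.42, 0.51), hsp-4 (-0.05, 0.95) nor sod-3 (0.01, 0.99) passed. Further lists, with no member passing on its own, were proteasome subunits (median 0.24, adjusted p = 0.00192, but 0.683 when estimated), DNA replication (-0.29, adjusted p = 0.014, but 0.545 when estimated) and oocyte and germline (-0.56, adjusted p = 0.0118, but 0.689 when estimated).

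After 8 h of high acrylamide SKN-1 and glutathione S-transferase lists were higher, and 5 of 5 yolk, 10 of 21 oocyte and 5 of 18 cell-cycle genes were lower. The SKN-1 list held 13 higher and 0 lower of 17 (14 and 0 over the list), with a median of 1.86 (adjusted p = 3.62e-26, and 0.0106 with an estimated correlation). Of 40 glutathione S-transferases 22 rose and 6 fell (25 and 7 over the list), with a median of 1.6 (adjusted p = 7.46e-20, and 0.0223 when estimated). W06H8.2 rose 109-fold (log2 change 6.76, SE 0.58, adjusted p = 7.8e-09). The genes gst-30, gsto-2, gst-12 and gst-5 rose 54.8-fold, 47.1-fold, 45.4-fold and 24.1-fold, nit-1 rose 17.3-fold, msra-1 13.1-fold, gst-4 5.71-fold and gcs-1 3.64-fold. The transferase gene ugt-13 rose 17.1-fold. Its list held 18 higher and 2 lower of 55 (22 and 4 over the list; adjusted p = 2.11e-07, but 0.123 when estimated). Cytochromes P450 gave 8 higher and 1 lower of 41 (11 and 3 over the list; adjusted p = 0.000767, but 0.116 when estimated). Antioxidant enzymes gave 4 higher and 0 lower of 18 (6 and 0 over the list), among them the superoxide dismutase gene sod-4, 2.45-fold (adjusted p = 0.00239, but 0.288 when estimated). Ferritin gene ftn-1 stayed 26.7-fold higher and clec-9 37.8-fold higher.

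Members of the metallothionein and cadmium response list parted at 8 h of acrylamide. The cadmium-responsive gene cdr-4 rose 8.27-fold (SE 0.32, adjusted p = 1.9e-07) and the heavy metal transporter gene hmt-1 rose 3.52-fold (SE 0.15, adjusted p = 4.6e-09). In contrast mtl-1 fell 3.10-fold (SE 0.37, adjusted p = 0.0046) and mtl-2 fell 3.02-fold (SE 0.39, adjusted p = 0.0092). The mtl-2 call was lost without replicate 1 of the high dose (log2 change -1.22, adjusted p = 0.074). The list held 3 higher and 2 lower of 10 (4 and 2 over the list; adjusted p = 0.00996, but 0.175 with an estimated correlation). At 4 h that list had not passed (3 higher and 3 lower, 3 and 3 over the list, adjusted p = 0.213).

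All 5 vitellogenins, the genes of the yolk lipoproteins, were lower at 8 h of high acrylamide (0 higher and 5 lower also over the list). Their median log2 change was -3.28 (adjusted p = 2.24e-06, but 0.116 with an estimated correlation). The transcripts of vit-4 and vit-6 fell 16-fold and 13.7-fold (SE 0.60 and 0.83, adjusted p = 4.1e-05 and 0.0037). Of 21 oocyte and germline genes 0 rose and 10 fell (0 and 16 over the list), with a median of -1.28 (adjusted p = 1.95e-08, but 0.302 when estimated). The eggshell chitin synthase gene chs-1 fell 5.81-fold (SE 0.49, adjusted p = 0.001). The egg surface gene egg-1 fell 3.75-fold (adjusted p = 0.0073), a call lost without replicate 1 of the control (adjusted p = 0.052) or replicate 2 of the high dose (adjusted p = 0.062). DNA replication and cell-cycle genes gave 0 higher and 5 lower of 18 (0 and 10 over the list), with the ribonucleotide reductase gene rnr-2 1.93-fold lower (median -0.62, adjusted p = 6.55e-05, but 0.297 when estimated).

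Intestine and body wall muscle lists were also lower at 8 h of acrylamide, calls lost with an estimated correlation (smallest adjusted p = 0.409). Of 11 intestine markers 0 rose and 5 fell (0 and 5 over the list), with act-5 5.98-fold and the protease gene cpr-1 2.67-fold lower (adjusted p = 0.0188, but 0.545 when estimated). Of 10 muscle markers 0 rose and 2 fell (0 and 4 over the list), with the troponin T gene mup-2 2.09-fold lower (adjusted p = 0.00262, but 0.409 when estimated). C-type lectins gave 6 higher and 24 lower of 115 (8 and 35 over the list), with clec-50 9.85-fold lower and clec-3 10.6-fold higher (adjusted p = 0.00348, but 0.376 when estimated). Among 9 epidermal antimicrobial peptide genes 2 rose and 0 fell (3 and 0 over the list), namely cnc-4 2.71-fold and nlp-31 2.41-fold (adjusted p = 0.044, but 0.454 when estimated). The hypoxia and hydrogen sulfide list held 0 higher and 3 lower of 8 (0 and 3 over the list), with sqrd-1 6.10-fold lower (adjusted p = 0.0213, but 0.415 when estimated). The genes nas-27, rips-1 and the enoyl-CoA hydratase gene ech-9 fell 17-fold, 11.7-fold and 15.1-fold. The actin 3' to 5' signal ratio, a measure of RNA integrity, had a log2 mean of 0.969 (SD 0.095, n = 3) in the control and 1.31 (SD 0.168, n = 3) at the high dose. The same ratio of GAPDH, a second such measure, was not higher, at 0.074 (SD 0.064) and -0.022 (SD 0.262).

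At lower acrylamide doses genes chosen at the high dose were followed. At 8 h of the low dose gst-30 was already higher by 3.63 on the log2 scale (SE 0.57, adjusted p = 0.00078), W06H8.2 34.2-fold (SE 0.58, adjusted p = 1e-05), gst-4 5.56-fold (SE 0.26, adjusted p = 3.3e-06) and nit-1 5.11-fold (SE 0.24, adjusted p = 2.6e-06). At the mid dose gst-30 rose 40.3-fold at 4 h and 61.1-fold at 8 h, and rips-1 fell 23.1-fold and 11.3-fold. The metallothionein gene mtl-1 fell 5.48-fold at the mid dose at 4 h (SE 0.37, adjusted p = 0.00012). At 4 h 26 probe sets were called at the low dose (25 higher, 1 lower), 264 at the mid dose (215 and 49) and 1020 at the high dose (514 and 506). At 8 h there were 54 (53 and 1), 397 (320 and 77) and 1450 (687 and 763). Under the authors' scaling the high dose split 711 higher and 465 lower at 4 h and 1050 and 714 at 8 h, and under quantile normalization the mid dose at 8 h split 340 and 152. In fits of only the compared groups the counts at 4 h were 0, 147 and 621. The count of 26 fell to 12 and 11 without replicates 1 and 2 of the control, and to 9 without replicate 3 of the low dose, 16 without its replicate 2. Without replicate 1 of the control at 8 h the high dose called 942. The trend over dose was called for 1209 probe sets at 4 h (626 higher, 583 lower) and 1846 at 8 h (892 and 954). These counts fell to 421 and 635 without replicate 2, and to 546 and 788 without replicate 3.

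**Figure D1:**
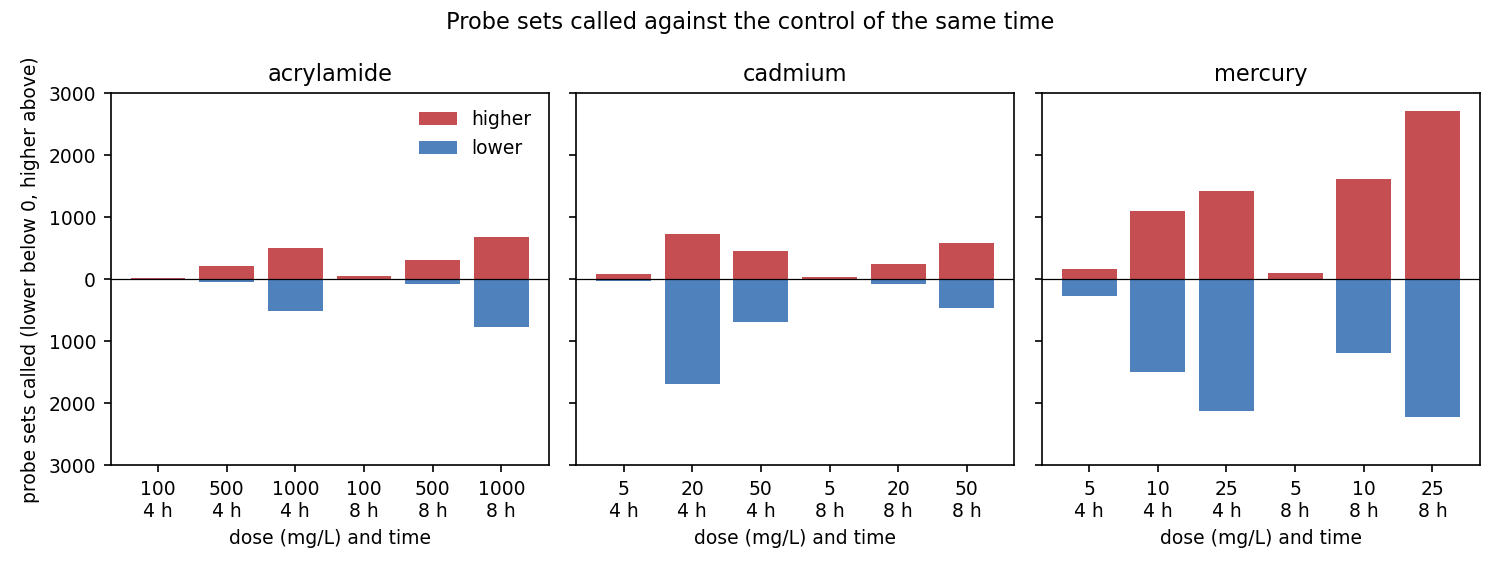
Number of probe sets called at an adjusted p under 0.05 (vertical axis) against dose (low, mid and high) for each chemical at 4 h and 8 h, with bars for higher above 0 and for lower below 0. The tallest pair of bars is that of high mercury at 8 h, with 2710 higher and 2222 lower, and the cadmium mid dose at 4 h, with 2407 calls, exceeds the high dose at 1150.

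Cadmium at the high dose for 4 h raised the lists of metal response and P450 genes and 4 of 18 heat shock genes. Of 10 genes in the metallothionein and cadmium response list 7 rose and 1 fell (7 and 1 over the list), with a median of 1.33 (adjusted p = 2.38e-08, and 0.0223 with an estimated correlation). The gene cdr-1 rose 53.2-fold (log2 change 5.73, SE 0.43, adjusted p = 1.5e-09). The metallothionein genes mtl-1 and mtl-2 rose 3.81-fold and 3.75-fold (SE 0.32 and 0.38, adjusted p = 0.00024 and 0.0015), and cdr-4 rose 13.4-fold. The zinc transporter genes cdf-2 and ttm-1 rose 5.3-fold and 3.17-fold, and ftn-1 rose 32.7-fold (SE 0.31, adjusted p = 9.3e-11). Their list of zinc, iron, copper and heme genes held 7 higher and 0 lower of 16 (7 and 1 over the list; adjusted p = 8.78e-07, but 0.0599 when estimated). Small heat shock genes hsp-16.41 and hsp-16.2 rose 32.4-fold and 22.1-fold (SE 0.69 and 0.54, adjusted p = 2.1e-05 and 3.1e-06), and hsp-70 rose 8.86-fold (SE 0.55, adjusted p = 0.00038). The whole list of 18 cytosolic heat shock genes did not pass (4 higher and 1 lower, 4 and 1 over the list, adjusted p = 0.182). Its median was -0.08 while its mean was 0.55 and the test pointed up. Under quantile normalization that list passed (adjusted p = 0.0114).

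The list of cytochromes P450 was higher at 4 h of high cadmium, with 9 members higher and 3 lower of 41 (12 and 3 over the list; adjusted p = 4.17e-05, and 0.044 with an estimated correlation). The genes cyp-13A4, cyp-14A4 and cyp-33C7 rose 25.6-fold, 14.4-fold and 13.9-fold. Of 39 glutathione S-transferases 13 rose and 5 fell (16 and 6 over the list), with gst-38 up 23-fold (adjusted p = 3.37e-05, but 0.297 when estimated). The SKN-1 list held 5 higher and 0 lower of 16 (7 and 1 over the list), with gcs-1 2.77-fold and gst-4 2.71-fold higher (adjusted p = 0.000171, but 0.116 when estimated). UDP-glucuronosyltransferases gave 11 higher and 4 lower of 50 (14 and 8 over the list), with ugt-1 up 5.75-fold and ugt-6 down 7.51-fold (adjusted p = 0.00406, but 0.418 when estimated). The genes clec-9, F08G2.5 and T08G5.1 rose 88.9-fold, 40.3-fold and 29.1-fold.

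The elongase, moulting and dehydrogenase lists were lower at 4 h of high cadmium, calls lost with an estimated correlation (smallest adjusted p = 0.297). The actin 3' to 5' signal ratio was higher there, with a log2 mean of 1.07 (SD 0.308, n = 3) against 0.645 (SD 0.184, n = 3) in the control. With it as a covariate, a fit chosen after the results were seen, 836 probe sets were called instead of 1150. The medians of elongase (-0.54 to -0.44), moulting (-0.81 to -0.89), dehydrogenase (-0.4 to -0.41), hypoxia (-0.71 to -0.74), muscle (-0.76 to -0.75) and ribosomal genes (-0.44 to -0.53) moved by under 1.5 times. Others went from -0.43 to -0.23 (DNA replication), -0.49 to -0.13 (oocyte), -0.46 to -0.19 (sperm) and 0.12 to 0 (UDP-glucuronosyltransferases). The fatty acid elongase genes elo-5 and elo-2 fell 5.31-fold and 4.05-fold, within a list of 15 with 0 higher and 5 lower (0 and 7 over the list; adjusted p = 0.0025, but 0.297 when estimated). The gene nas-27 fell 15.3-fold (SE 0.45, adjusted p = 1.8e-06) and acox-1.2 fell 13.1-fold (SE 0.41, adjusted p = 7.9e-07). Of 19 moulting genes 0 rose and 5 fell (1 and 10 over the list), among them mlt-10 2.86-fold and the protease gene nas-37 2.62-fold (adjusted p = 0.000296, but 0.302 when estimated). Short-chain dehydrogenases gave 1 higher and 7 lower of 26 (1 and 9 over the list; adjusted p = 0.00239, but 0.336 when estimated). The hypoxia and hydrogen sulfide list held 0 higher and 4 lower of 8 (0 and 4 over the list), with the prolyl hydroxylase gene phy-2 2.95-fold lower (adjusted p = 0.0152, but 0.299 when estimated). Body wall muscle markers gave 0 higher and 1 lower of 10 (0 and 4 over the list; adjusted p = 0.0121, but 0.554 when estimated). Medians of ribosomal (-0.44, adjusted p = 0.0033) and sperm genes (-0.46, adjusted p = 0.00492) were lower, with adjusted p = 0.818 and 0.689 when estimated. Those of DNA replication (-0.43, adjusted p = 0.039) and oocyte genes (-0.49, adjusted p = 0.0483) were lower, with adjusted p = 0.711 and 0.711 when estimated. At most 1 member of each of these 4 lists passed on its own, and without the array apart described below the last 2 lists were not called (adjusted p = 0.0501 and 0.0548). Under quantile normalization the calls of ribosomal (adjusted p = 0.334) and DNA replication genes (0.102) were lost. The 11 intracellular pathogen response genes were higher as a list with no member called (median 0.30, adjusted p = 0.0121, but 0.267 when estimated), a call lost under quantile normalization (adjusted p = 0.18). For hsp-4, of the endoplasmic reticulum, the change was 0.79 (adjusted p = 0.083), and it passed under quantile normalization (0.0024), under the authors' scaling (0.0029) and without replicate 3 of the high dose (0.02). Changes of hsp-6 (-0.83, adjusted p = 0.092) and sod-3 (0.45, adjusted p = 0.36) did not pass.

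After 8 h of high cadmium the lists of metal response and P450 genes were higher, 4 of 18 heat shock genes rose, and 5 of 5 yolk and 16 of 21 oocyte genes fell. The metallothionein and cadmium response list held 5 higher and 0 lower of 10 (5 and 0 over the list), with a median of 1.4 (adjusted p = 1.54e-10, and 0.0172 with an estimated correlation). The gene cdr-1 was 49.7-fold higher (SE 0.43, adjusted p = 1.5e-09), mtl-1 5.95-fold (SE 0.32, adjusted p = 5.7e-06) and mtl-2 4.16-fold (SE 0.38, adjusted p = 7e-04). The zinc list held 5 higher and 1 lower of 16 (7 and 2 over the list), with ftn-1 8.77-fold, cdf-2 6.64-fold and the zinc-sensing receptor gene hizr-1 3.00-fold higher (adjusted p = 0.000203, but 0.148 when estimated). The heat shock genes hsp-16.41, hsp-16.2 and hsp-70 rose 42.5-fold, 23.5-fold and 14.2-fold (SE 0.69, 0.54 and 0.55), while their list of 18 did not pass (4 higher and 0 lower, 4 and 0 over the list, median -0.20, mean 0.63, direction up, adjusted p = 0.18). Cytochromes P450 gave 11 higher and 2 lower of 41 (13 and 3 over the list), with cyp-13A4 up 49.3-fold and cyp-33C7 up 17-fold (adjusted p = 9.11e-08, and 0.0194 when estimated). The SKN-1 list held 4 higher and 0 lower of 16 (9 and 0 over the list), with gst-4 3.63-fold and gcs-1 2.64-fold higher (adjusted p = 3.76e-08, and 0.0223 when estimated). Glutathione S-transferases gave 14 higher and 0 lower of 39 (17 and 2 over the list), with gst-38 up 30.2-fold (adjusted p = 1.15e-09, but 0.116 when estimated). UDP-glucuronosyltransferases gave 16 higher and 3 lower of 50 (19 and 8 over the list), with ugt-1 up 10.3-fold (adjusted p = 2.79e-06, but 0.175 when estimated). Antioxidant enzymes gave 2 higher and 0 lower of 17 (2 and 0 over the list), with msra-1 up 7.21-fold (adjusted p = 0.0118, but 0.515 when estimated).

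Yolk gene vit-5 fell 11.4-fold and vit-4 fell 11.3-fold at 8 h of high cadmium (SE 0.43 and 0.38, adjusted p = 4.7e-06 and 5.4e-07). All 5 vitellogenins were lower, also over the list, with a median of -2.28 (adjusted p = 2.77e-08, but 0.0821 with an estimated correlation). Of 21 oocyte and germline genes 0 rose and 16 fell (0 and 20 over the list), with a median of -1.63 (adjusted p = 5.96e-18, but 0.0974 when estimated). Among these chs-1 fell 4.69-fold, egg-1 4.50-fold, the yolk receptor gene rme-2 4.28-fold and the oocyte RNA-binding gene puf-5 4.09-fold. DNA replication and cell-cycle genes gave 0 higher and 5 lower of 17 (0 and 13 over the list; median -0.82, adjusted p = 8.78e-07, but 0.337 when estimated). Cuticle collagens gave 1 higher and 5 lower of 120 (0 and 3 over the list), with col-137 5.79-fold and col-156 4.97-fold lower (adjusted p = 0.0033, but 0.689 when estimated). The hypoxia and hydrogen sulfide list held 0 higher and 3 lower of 8 (0 and 3 over the list), with rhy-1 2.89-fold lower (adjusted p = 0.00348, but 0.199 when estimated). Sperm genes (median -0.50, adjusted p = 8.57e-05) and proteasome genes (-0.36, adjusted p = 0.0118) were lower as lists with no member called, with adjusted p = 0.561 and 0.758 when estimated. Body wall muscle markers gave 0 higher and 1 lower of 10 (0 and 1 over the list; adjusted p = 0.024, but 0.624 when estimated). The genes rips-1 and nas-27 fell 10.4-fold and 8.26-fold. The log2 actin ratio was 0.876 (SD 0.25, n = 3) in the control and 1.1 (SD 0.376, n = 3) at the high dose. That of GAPDH was 0.01 (SD 0.06) and 0.071 (SD 0.176).

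In 4 further lists called higher at 8 h of high cadmium most members did not pass, and none of the 4 held with an estimated correlation. Among 9 epidermal antimicrobial peptide genes 3 rose and 0 fell (3 and 0 over the list), with nlp-29 2.79-fold higher (adjusted p = 0.00109, but 0.302 when estimated). Of 11 intracellular pathogen response genes 2 rose and 0 fell (5 and 0 over the list), with pals-6 4.68-fold higher (adjusted p = 0.000335, but 0.106 when estimated). The endoplasmic reticulum list held 1 higher and 0 lower of 19 (2 and 0 over the list), the choline kinase gene ckb-2 at 3.46-fold (adjusted p = 0.0191, but 0.507 when estimated). Neuron markers gave 1 higher and 0 lower of 12 (2 and 0 over the list; adjusted p = 0.0106, but 0.21 when estimated). The genes hsp-4 (0.53, adjusted p = 0.3), hsp-6 (-0.43, 0.45) and sod-3 (0.42, 0.43) did not pass. Intestine markers did not pass either (2 higher, 0 lower, adjusted p = 0.374).

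At the low cadmium dose cdr-1 rose 60.5-fold at 4 h and 42.5-fold at 8 h (SE 0.43, adjusted p = 2.3e-09 and 1.1e-08), and cyp-13A4 rose 39.3-fold and 26-fold. The gene mtl-1 rose 4.75-fold and 4.76-fold (SE 0.32, adjusted p = 0.00013 and 0.00028), and mtl-2 rose 4.89-fold and 5.19-fold (SE 0.38, adjusted p = 8e-04 and 0.00079). At the low dose hsp-70 did not pass (log2 change 1.63 at 4 h, adjusted p = 0.41, and 0.44 at 8 h, adjusted p = 1). The heat shock gene hsp-16.41 rose there by 3.77 at 4 h (SE 0.69, adjusted p = 0.0032, but 0.071 without replicate 3), and at 8 h its change was 2.64 (adjusted p = 0.19). Calls at 4 h numbered 99 at the low dose (80 higher, 19 lower), 2407 at the mid dose (725 and 1682) and 1150 at the high dose (459 and 691). At 8 h they numbered 47 (41 and 6), 326 (256 and 70) and 1047 (588 and 459). Under the authors' scaling the splits were 764 and 956 at the mid dose and 817 and 472 at the high dose at 4 h, and 843 and 379 at the high dose at 8 h. Under quantile normalization they were 797 and 1100 and 715 and 652 at 4 h. The median of all probe sets moved from -0.12 to 0.10 at the high dose at 4 h under the authors' scaling, from -0.11 to 0.02 at the mid dose at 8 h, and from -0.12 to 0.02 at the high dose at 8 h.

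The cadmium counts varied with the array left out, in fits that also have less power. Replicate 1 of the mid dose at 4 h correlated on average at 0.774 with the other cadmium arrays, the lowest value of the series. Without it the mid dose at 4 h called 293 probe sets, and without replicate 2 it called 7071. Without replicates 1, 2 and 3 of the control it called 958, 1094 and 1341, and in a fit of only those groups 75. The genes cdr-1, mtl-1 and mtl-2 were 78.2-fold, 3.48-fold and 6.02-fold higher there (n = 2, adjusted p = 3e-09, 0.0023 and 0.00026), and in the fit of only those groups the calls of mtl-1 (adjusted p = 0.18) and mtl-2 (0.16) were lost. The high dose at 4 h called 604 and 746 without replicates 1 and 2 of the control and 699 without its own replicate 3. At 8 h it called 651 and 596 without replicates 1 and 2 of the control, 661 and 651 without its own replicates 1 and 2, and 1783 in a fit of only those groups. The mid dose at 8 h called 217 without replicate 1 of the control, 211 without its own replicate 1 and 504 under quantile normalization. Without its replicate 3 the low dose called 59 at 4 h and 28 at 8 h. The dose trend was called for 2045 probe sets at 4 h (703 higher, 1342 lower) and 1533 at 8 h (754 and 779). With the authors' scaling these split 1141 and 730, and 1156 and 563, and under quantile normalization the first split 895 and 949. The trend at 4 h fell to 606 without replicate 1 and 676 without replicate 3, and that at 8 h to 741, 920 and 919 without replicates 1, 2 and 3.

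Mercury at the high dose for 4 h raised 7 of 18 heat shock, 11 of 17 SKN-1 list and 5 of 9 epidermal peptide genes. The heat shock genes hsp-16.41, hsp-70 and hsp-16.2 rose 73.1-fold, 59.1-fold and 43.9-fold (SE 0.30, 0.26 and 0.35, adjusted p = 1.2e-14, 1.5e-15 and 5.4e-12). Of 18 cytosolic heat shock genes 7 rose and 2 fell (8 and 2 over the list; adjusted p = 0.000303, but 0.302 with an estimated correlation). The SKN-1 list held 11 higher and 0 lower of 17 (13 and 0 over the list), with a median of 1.3 (1.32 with the actin ratio as a covariate; adjusted p = 1.02e-13, and 0.0223 when estimated). The genes gst-30 and ugt-13 rose 36.9-fold and 15-fold, gst-4 6.13-fold and gcs-1 5.07-fold. Glutathione S-transferases gave 22 higher and 9 lower of 39 (24 and 9 over the list; adjusted p = 2.6e-08, but 0.116 when estimated). Antioxidant enzymes gave 5 higher and 2 lower of 17 (6 and 3 over the list), with msra-1 7.48-fold and sod-3 1.74-fold higher (adjusted p = 0.0428, but 0.453 when estimated). Of 10 metallothionein and cadmium response genes 6 rose and 1 fell (6 and 1 over the list; adjusted p = 0.000767, and 0.0253 when estimated). In it kreg-1 rose 36.3-fold, cdr-4 9.98-fold, cdr-1 7.59-fold (SE 0.29, adjusted p = 1.6e-08) and mtl-2 2.17-fold (SE 0.28, adjusted p = 0.0038), and cdr-2 fell 2.55-fold. The change of mtl-1 was 0.74 (adjusted p = 0.039), lost without control replicate 2 (0.16) or 3 (0.11) or high-dose replicate 1 (0.066) or 3 (0.15), and with no filter (0.059). Of 9 epidermal antimicrobial peptide genes 5 rose and 0 fell (5 and 0 over the list), with cnc-4 7.84-fold and nlp-29 3.76-fold higher (median 1.77, and 0.93 with the actin ratio as a covariate; adjusted p = 0.000179, but 0.266 when estimated). The endoplasmic reticulum chaperone gene hsp-4 rose 1.92-fold (SE 0.19, adjusted p = 0.00038), while hsp-6 did not pass (-0.29, adjusted p = 0.26).

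Yolk, elongase, intestine, moulting and muscle lists were lower at 4 h of high mercury, calls lost with an estimated correlation (smallest adjusted p = 0.302). The actin 3' to 5' signal ratio was higher there (log2 mean 1.31, SD 0.129, n = 3) than in the control (0.855, SD 0.078, n = 3). With it as covariate, a fit chosen after the results, 1208 probe sets were called instead of 3554. As no control ratio reached the high dose's, this decides nothing. The medians went from -2.2 to -1.92 (yolk), -0.43 to -0.27 (elongases), -0.77 to -0.47 (intestine), -0.61 to -0.58 (moulting) and -0.62 to -0.46 (muscle). Members called lower went from 5 to 1, 7 to 3, 6 to 2, 10 to 0 and 7 to 1, while the median SE rose, for yolk genes from 0.44 to 0.63. All 5 vitellogenins were lower, also over the list, with a median of -2.20 and vit-6 8.13-fold lower (adjusted p = 0.000812, but 0.302 when estimated). The elongase genes elo-5 and elo-6 fell 10.6-fold and 5.89-fold, in a list of 15 with 1 higher and 7 lower (1 and 8 over the list; adjusted p = 0.028, but 0.374 when estimated). That call was lost under quantile normalization (adjusted p = 0.129). The genes nas-27 and acox-1.2 fell 14.3-fold and 13.6-fold (SE 0.36 and 0.23, adjusted p = 4.9e-09 and 1.6e-12), and the lectin gene clec-56 fell 13.5-fold. Of 24 lysozymes and saposin-like genes 4 rose and 9 fell (4 and 9 over the list), with ilys-5 5.1-fold lower (adjusted p = 0.00508, but 0.302 when estimated). Intestine markers gave 1 higher and 6 lower of 11 (1 and 6 over the list), with the proton pump gene vha-6 3.00-fold and the esterase gene ges-1 2.34-fold lower (adjusted p = 0.0033, but 0.396 when estimated). Body wall muscle markers gave 0 higher and 7 lower of 10 (0 and 9 over the list), with mup-2 1.98-fold and the troponin I gene unc-27 1.89-fold lower (adjusted p = 0.00097, but 0.337 when estimated). Moulting genes gave 0 higher and 10 lower of 19 (0 and 12 over the list), with mlt-10 2.08-fold lower (adjusted p = 0.00445, but 0.353 when estimated).

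After 8 h of high mercury more probe sets were called than for any other single dose against control. F08G2.5 rose 126-fold, hsp-16.41 84.7-fold, hsp-70 67.2-fold and hsp-16.2 48.5-fold (SE 0.28, 0.30, 0.26 and 0.35). Of 18 cytosolic heat shock genes 10 rose and 2 fell (10 and 2 over the list; adjusted p = 0.00045, but 0.319 with an estimated correlation). The endoplasmic reticulum list passed, with 10 higher and 0 lower of 19 (10 and 0 over the list; adjusted p = 0.00172, but 0.297 when estimated). In it ckb-2 rose 15.5-fold, hsp-4 2.79-fold and the stress kinase gene pek-1 2.12-fold. Of 33 proteasome genes 7 rose and 0 fell (5 and 0 over the list), with rpn-2 1.96-fold higher (adjusted p = 0.00271, but 0.703 when estimated). The SKN-1 list held 15 higher and 0 lower of 17 (15 and 0 over the list), with a median of 1.58 (adjusted p = 9.77e-13, and 0.0223 when estimated). Glutathione S-transferases gave 26 higher and 8 lower of 39 (27 and 9 over the list), with gst-30 up 30.2-fold (adjusted p = 2.11e-06, but 0.181 when estimated). Antioxidant enzymes gave 4 higher and 2 lower of 17 (6 and 2 over the list), with msra-1 11.4-fold and sod-4 3.68-fold higher (adjusted p = 0.0481, but 0.468 when estimated). The metallothionein and cadmium response list held 6 higher and 1 lower of 10 (8 and 1 over the list; adjusted p = 0.00239, and 0.044 when estimated). There kreg-1 rose 43.2-fold, cdr-4 17.2-fold, cdr-1 5.34-fold and mtl-1 2.11-fold (SE 0.48, 0.28, 0.29 and 0.26). The change of mtl-2 was 0.70 (adjusted p = 0.055), which passed with quantile normalization (0.0083), the authors' scaling (0.047) and without control replicates 2 (0.031) or 3 (0.025) or high-dose replicate 1 (0.034). Epidermal antimicrobial peptide genes gave 6 higher and 0 lower of 9 (7 and 0 over the list), with cnc-4 higher by 4.01 on the log2 scale and nlp-29 7.44-fold higher (median 1.92, adjusted p = 6.53e-06, but 0.175 when estimated). Neuron markers gave 6 higher and 0 lower of 12 (7 and 0 over the list), among them the neuropeptide processing genes egl-3, 2.19-fold, and egl-21, 1.65-fold (adjusted p = 0.0163, but 0.149 when estimated). Neither hsp-6 (0.04, adjusted p = 0.89) nor sod-3 (0.21, adjusted p = 0.39) passed.

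Yolk genes had the largest decreases at 8 h of high mercury: vit-6, vit-4 and vit-5 fell 28-fold, 25.1-fold and 22.5-fold (SE 0.44, 0.43 and 0.43, adjusted p = 2.4e-09, 3e-09 and 5.6e-09). All 5 vitellogenins were lower, also over the list, with a median of -4.49 (adjusted p = 2.12e-07, but 0.116 with an estimated correlation). Of 21 oocyte and germline genes 0 rose and 16 fell (0 and 17 over the list), with puf-5 3.71-fold and rme-2 3.52-fold lower (adjusted p = 1.15e-09, but 0.0812 when estimated). Cuticle collagens gave 3 higher and 34 lower of 121 (3 and 34 over the list), with col-137 10.3-fold lower and col-90 4.83-fold higher (adjusted p = 8.78e-07, but 0.445 when estimated). Muscle markers gave 0 higher and 6 lower of 10 (0 and 7 over the list), with unc-27 3.88-fold, mup-2 3.02-fold and the myosin gene unc-54 2.43-fold lower (adjusted p = 0.000303, but 0.302 when estimated). Intestine markers gave 0 higher and 6 lower of 11 (1 and 7 over the list), with vha-6 3.11-fold and the gut transcription factor gene elt-2 2.12-fold lower (adjusted p = 0.0025, but 0.376 when estimated). The elongase gene elo-5 fell 14.3-fold, in a list with 1 higher and 7 lower of 15 (1 and 8 over the list; adjusted p = 0.00546, but 0.266 when estimated). C-type lectins gave 13 higher and 36 lower (14 and 37 over the list; adjusted p = 0.000812, but 0.207 when estimated), and lysozymes and saposin-like genes gave 5 higher and 13 lower of 24 (5 and 14 over the list; adjusted p = 0.000981, but 0.21 when estimated).

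At 8 h of high mercury the hypoxia and hydrogen sulfide list held 0 higher and 6 lower of 8 (0 and 6 over the list), with cysl-3 2.43-fold, sqrd-1 2.38-fold and rhy-1 2.24-fold lower (adjusted p = 0.00207, but 0.116 with an estimated correlation). DNA replication genes gave 0 higher and 8 lower of 17 (1 and 8 over the list), with cdk-1 1.71-fold lower (adjusted p = 0.0108, but 0.553 when estimated). Moulting genes gave 2 higher and 8 lower of 19 (3 and 8 over the list), with mlt-10 2.81-fold lower (adjusted p = 0.0481, but 0.545 when estimated). Hedgehog-related genes gave 5 higher and 14 lower of 36 (5 and 16 over the list), with wrt-6 2.57-fold lower (adjusted p = 0.0363, but 0.64 when estimated). Sperm genes gave 0 higher and 3 lower of 59 (0 and 0 over the list; median -0.29, adjusted p = 0.00788, but 0.689 when estimated). Cytochromes P450 did not pass (10 higher, 7 lower of 40, adjusted p = 0.904). The actin 3' to 5' signal ratio was higher at 8 h too: its log2 mean was 1.01 (SD 0.097, n = 3) in the control and 1.53 (SD 0.127, n = 3) at the high dose. That of GAPDH was not higher, at 0.165 (SD 0.047) and 0.163 (SD 0.15). With the actin ratio as covariate 2557 probe sets were called, not 4932, which as at 4 h decides nothing.

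**Figure D2:**
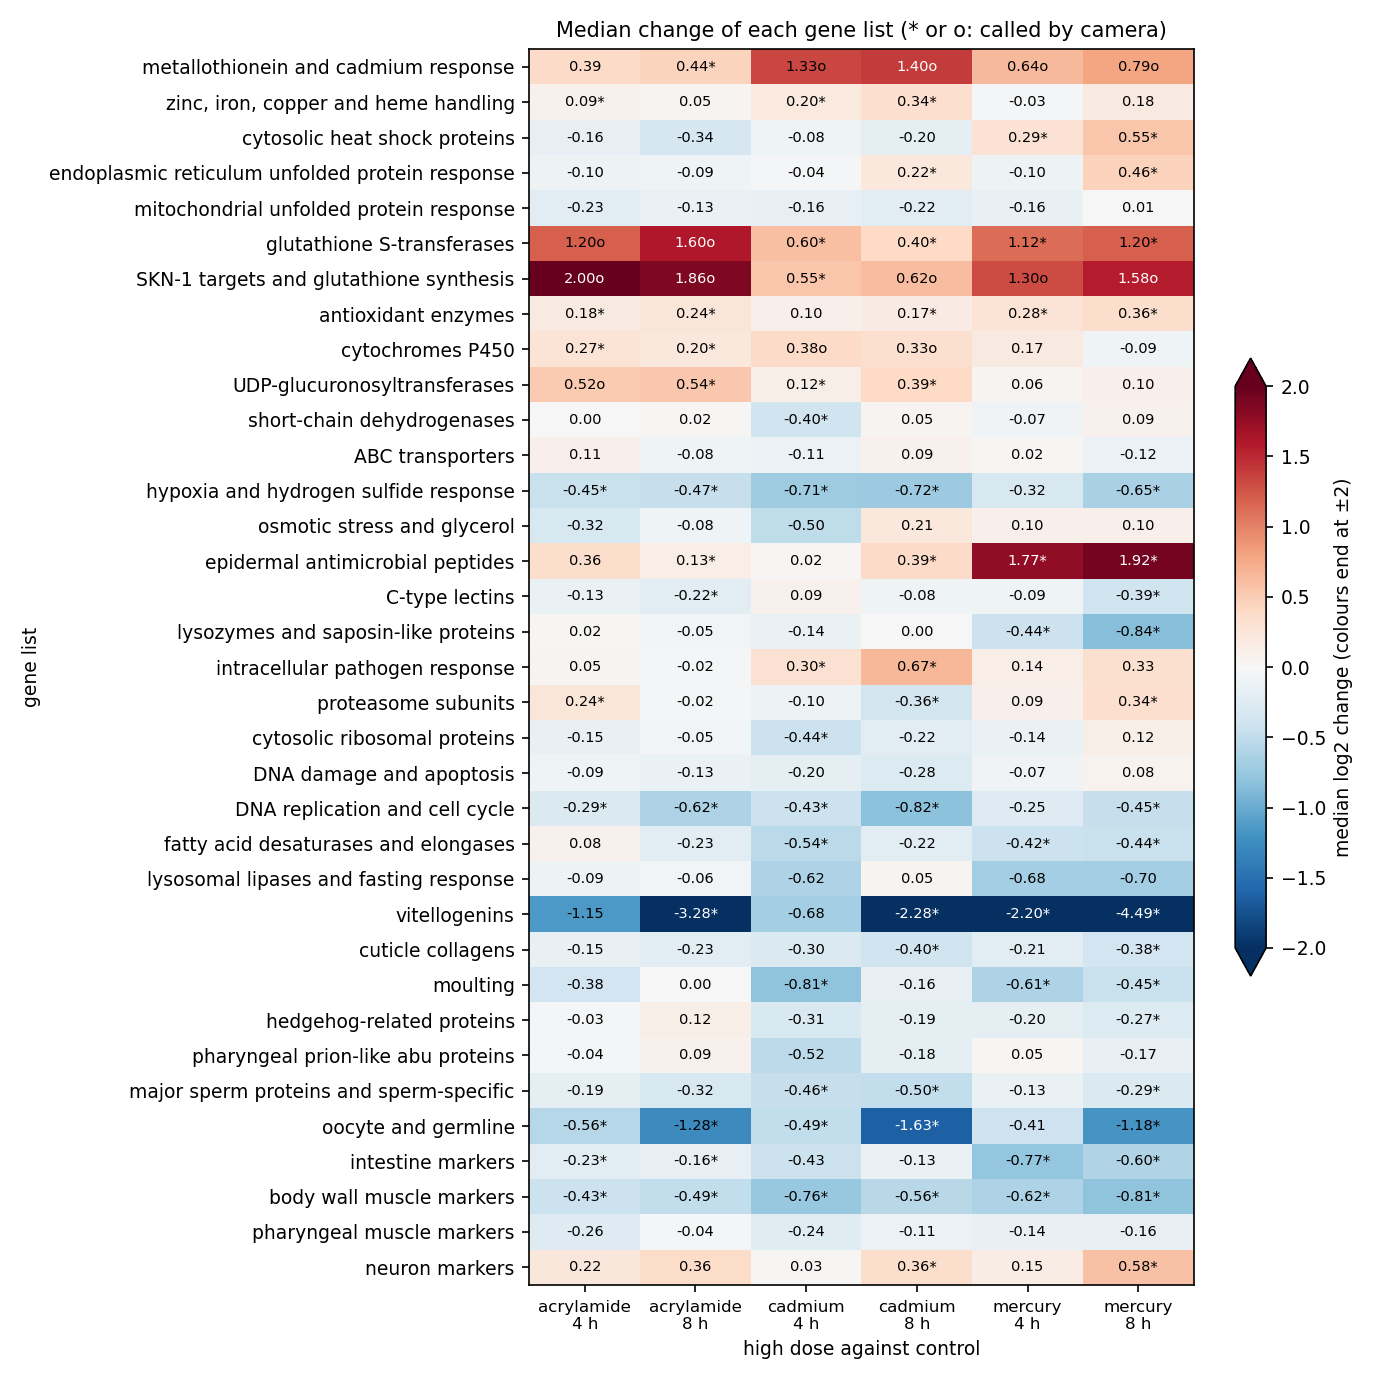
Median log2 change at the high dose against control for each of the 35 gene lists (vertical axis) in each chemical and time (horizontal axis), with colours from lower to higher ending at -2 and 2. A circle marks a list called with the preset and the estimated correlation and an asterisk a list called with the preset correlation only, and vitellogenins at 8 h of mercury have the lowest median, -4.49.

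At 4 h of the low mercury dose clec-9 rose 74.8-fold (SE 0.18, adjusted p = 8.8e-20), hsp-16.41 37.6-fold (SE 0.30, adjusted p = 1.7e-12), gst-30 9.56-fold, hsp-70 7.86-fold and gst-4 4.33-fold. At 8 h of that dose hsp-16.41 was 4.54-fold higher (adjusted p = 2e-04), while hsp-70 (log2 change 0.55, adjusted p = 0.66) and gst-30 (1.07, adjusted p = 0.15) did not pass. The low dose at 8 h less that at 4 h was not tested. At the mid dose hsp-70 rose 96.6-fold at 4 h and 73.6-fold at 8 h. Calls at 4 h numbered 428 at the low dose (166 higher, 262 lower), 2595 at the mid dose (1099 and 1496) and 3554 at the high dose (1433 and 2121). At 8 h they numbered 111 (110 and 1), 2814 (1627 and 1187) and 4932 (2710 and 2222). At 4 h the authors' scaling gave splits of 252 and 220, 1505 and 1346, and 1844 and 1817, and quantile normalization split the low dose 257 and 231. The median of all probe sets at the low dose at 4 h moved from -0.04 to 0.06 under the authors' scaling. The low dose called 283 at 4 h without control replicate 1. At 8 h it called 54 without control replicate 3, 68 without its own replicate 3, 72 in a fit of only those groups and 178 with the block. The mid dose at 8 h called 1847 without its replicate 3. The dose trend was called for 4156 probe sets at 4 h (1762 higher, 2394 lower) and 5893 at 8 h (3207 and 2686). Without replicate 2 these fell to 2120 and 3620, and without replicate 3 the second fell to 3875.

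Whether the high-dose effect differed between 8 h and 4 h was tested directly. Of 5 vitellogenins, vit-4 and vit-5 (chosen after values were seen) passed with each metal and the other 3 did not (adjusted p from 0.064 to 0.99). With acrylamide none did (0.83 to 1), at -2.07 to -2.81 with larger SE (0.73 to 1.17). For vit-4 the difference was -2.82 with cadmium (SE 0.53, adjusted p = 0.015) and -2.98 with mercury (SE 0.61, adjusted p = 0.019). In fits of fewer arrays these calls were lost without replicates 1, 2 and 3 for cadmium (-2.67, -2.52 and -3.28, adjusted p = 0.3, 0.13 and 0.15) and without replicates 2 and 3 for mercury (-2.89 and -2.56, adjusted p = 0.11 and 0.41). Without a pseudocount the cadmium call was lost too (adjusted p = 0.12). For vit-5 the differences were -2.84 (SE 0.61, adjusted p = 0.046) and -2.65 (SE 0.61, 0.035), lost without replicates 1, 2 and 3 (0.37, 0.51 and 0.17, and 0.082, 0.091 and 0.44), without a pseudocount (0.76 and 0.16), with no filter (0.077 and 0.058) and, for cadmium, under the authors' scaling (0.05). With cadmium the P450 gene cyp-37B1 went the other way (3.01, SE 0.47, adjusted p = 0.0031), a call lost without replicates 1 (0.2) and 3 (0.052). With mercury gpdh-1, of glycerol synthesis, had a higher effect at 8 h (1.68, SE 0.32, adjusted p = 0.017), lost without replicates 2 (0.3) and 3 (0.39). For acrylamide limma called 0 probe sets, with 674 at an unadjusted p under 0.05. For cadmium it called 38 (28 higher, 10 lower) and for mercury 126 (66 and 60). Under the authors' scaling the splits were 27 and 16 for cadmium and 74 and 148 for mercury, and under quantile normalization 102 and 170 for mercury. The cadmium count was 63 under quantile normalization, 21 without a pseudocount, 22 with no filter and 75 without the array apart. The mercury count was 409 with replicate number as a block, 67 with no filter, and acrylamide's was 8, 3 and 2 under quantile normalization, the authors' scaling and the block. The median of all probe sets for mercury moved from 0.09 to -0.02 under the authors' scaling. Without replicates 1, 2 and 3 the cadmium count was 2, 10 and 11, the mercury count was 3 and 0 without replicates 2 and 3, and the acrylamide count was 12 without replicate 1.

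More calls were shared between the chemicals than expected if calls were independent, though most calls were not shared by all 3. The number called higher in all 3 series at 4 h was 128 probe sets of 108 genes (1.11 expected). They include clec-9, W06H8.2, ftn-1, cdr-4 and msra-1. In the lower direction 221 probe sets of 175 genes were shared (3.15 expected), including nas-27, acox-1.2 and elo-5. At 8 h 186 probe sets of 152 genes were shared higher (3.68 expected), including clec-9, cdr-4, msra-1 and gst-30, and 179 of 136 genes lower (3.21 expected), including vit-4, vit-5, rips-1 and nas-27. In pairs at 8 h cadmium and mercury shared 395 higher (95.6 expected, odds ratio 13.5) and 349 lower (64.4 expected, 24.2). Mercury and acrylamide shared 488 higher (109 expected, odds ratio 18.4) and 533 lower (108 expected, 18.3). Cadmium and acrylamide shared 217 higher (21.7 expected, odds ratio 23.9) and 191 lower (21.7 expected, odds ratio 19). At 4 h the 6 odds ratios lay between 23.3 and 35.5. The largest adjusted p of the 12 exact tests was 8.41e-131. At 4 h cadmium and mercury shared 293 higher, 464 under quantile normalization and 506 under the authors' scaling, and cadmium and acrylamide 155, then 252 and 260. At 8 h cadmium and acrylamide shared 364 and 360 higher under these, and mercury and acrylamide 759 under the former. For lower calls the authors' scaling raised the odds ratios at 4 h from 35.5 to 61.8 (cadmium and mercury) and from 27.7 to 45 (cadmium and acrylamide), and that of cadmium and mercury at 8 h to 37.7.

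Differences between chemicals were tested on the effects at 8 h of the high dose, which is not matched between them. Genes were named after their values were seen, and differences of dim genes depend on the pseudocount. Against mercury, cadmium gave higher cyp-13A4 (5.80, SE 0.46, adjusted p = 1.3e-14), ugt-1 (3.41, SE 0.36, adjusted p = 1.1e-09) and cdr-1 (3.22, SE 0.54, adjusted p = 4.1e-05). The antimicrobial gene cnc-4 was lower (-3.62, SE 0.58, adjusted p = 1.6e-05). Against acrylamide, cadmium gave higher F08G2.5 (5.79, SE 0.55, adjusted p = 5.1e-12), cdr-1 (5.13, SE 0.54, adjusted p = 1.4e-10) and mtl-1 (4.21, SE 0.46, adjusted p = 5.4e-10) and lower gst-12 (-5.51, SE 0.54, adjusted p = 1.3e-11). Mercury gave higher hsp-70 (5.87, SE 0.57, adjusted p = 2.6e-11) and kreg-1 (5.24, SE 0.60, adjusted p = 2.3e-09) and lower gst-31 (-3.48, SE 0.38, adjusted p = 5e-10) than acrylamide. In all, 599 probe sets differed between cadmium and mercury (376 higher, 223 lower with cadmium), 432 between cadmium and acrylamide (285 and 147) and 595 between mercury and acrylamide (330 and 265). The first split was 567 and 157 under the authors' scaling and the last 296 and 404. The median of all probe sets moved from -0.16 to 0.01 and from 0.08 to -0.05 in these, and to -0.05 in the first under quantile normalization. Without replicate 2 the counts were about 120, 166 and 196, and without replicate 3 they were 292, 266 and 196.

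Unexposed worms changed over the incubation in each series. Most yolk, sperm and oocyte genes rose and most moulting genes fell between 0 h and 8 h, list calls lost with an estimated correlation (smallest adjusted p = 0.0808). All 5 vitellogenins rose in each series, also over the list, with medians of 4.88, 5.68 and 3.98 in the acrylamide, cadmium and mercury series. Of the sperm genes 49 of 60, 46 of 59 and 50 of 59 rose (49, 47 and 50 over the list), with medians of 2.15, 2.02 and 1.63. Of 21 oocyte and germline genes 18, 20 and 19 rose (20, 20 and 19 over the list), with medians of 1.64, 2.15 and 1.55. Of 19 moulting genes 13, 16 and 16 fell (14, 16 and 16 over the list), with medians of -1.57, -1.51 and -1.62. The camera tests gave adjusted p = 1.85e-07, 3.98e-12 and 1.2e-06 for vitellogenins, 4.61e-27, 4.81e-26 and 2.07e-31 for sperm genes, 2.45e-11, 6.06e-18 and 1.07e-15 for oocyte genes, and 0.00142, 1.03e-10 and 1.95e-08 for moulting genes. The acrylamide series gave adjusted p = 0.123, 0.272, 0.413 and 0.742 when estimated. The collagen gene col-19 rose by 5.12, 5.05 and 4.29 (SE 0.78, 0.42 and 0.23), and dpy-7, another collagen gene, changed by -3.77, -3.91 and -3.26 (SE 0.88, 0.43 and 0.23), both chosen after their values were seen. Without replicate 3 the dpy-7 call of the acrylamide series was lost (adjusted p = 0.066). In all 5722 probe sets changed in the acrylamide series (1768 higher, 3954 lower), 3250 in the cadmium series (1792 and 1458) and 6503 in the mercury series (1908 and 4595). Under the authors' scaling the first split 2686 and 1711 and the last 2797 and 2358, and under quantile normalization 1933 and 2062 and 2220 and 2844. The median of all probe sets moved from -0.22 to 0.08 and from -0.22 to 0.03 under the authors' scaling, and to -0.10 and -0.09 under quantile normalization. Without replicates 2 and 3 the acrylamide series called 2432 and 1855, and without replicate 1 the cadmium series called 1949.

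**Figure D3:**
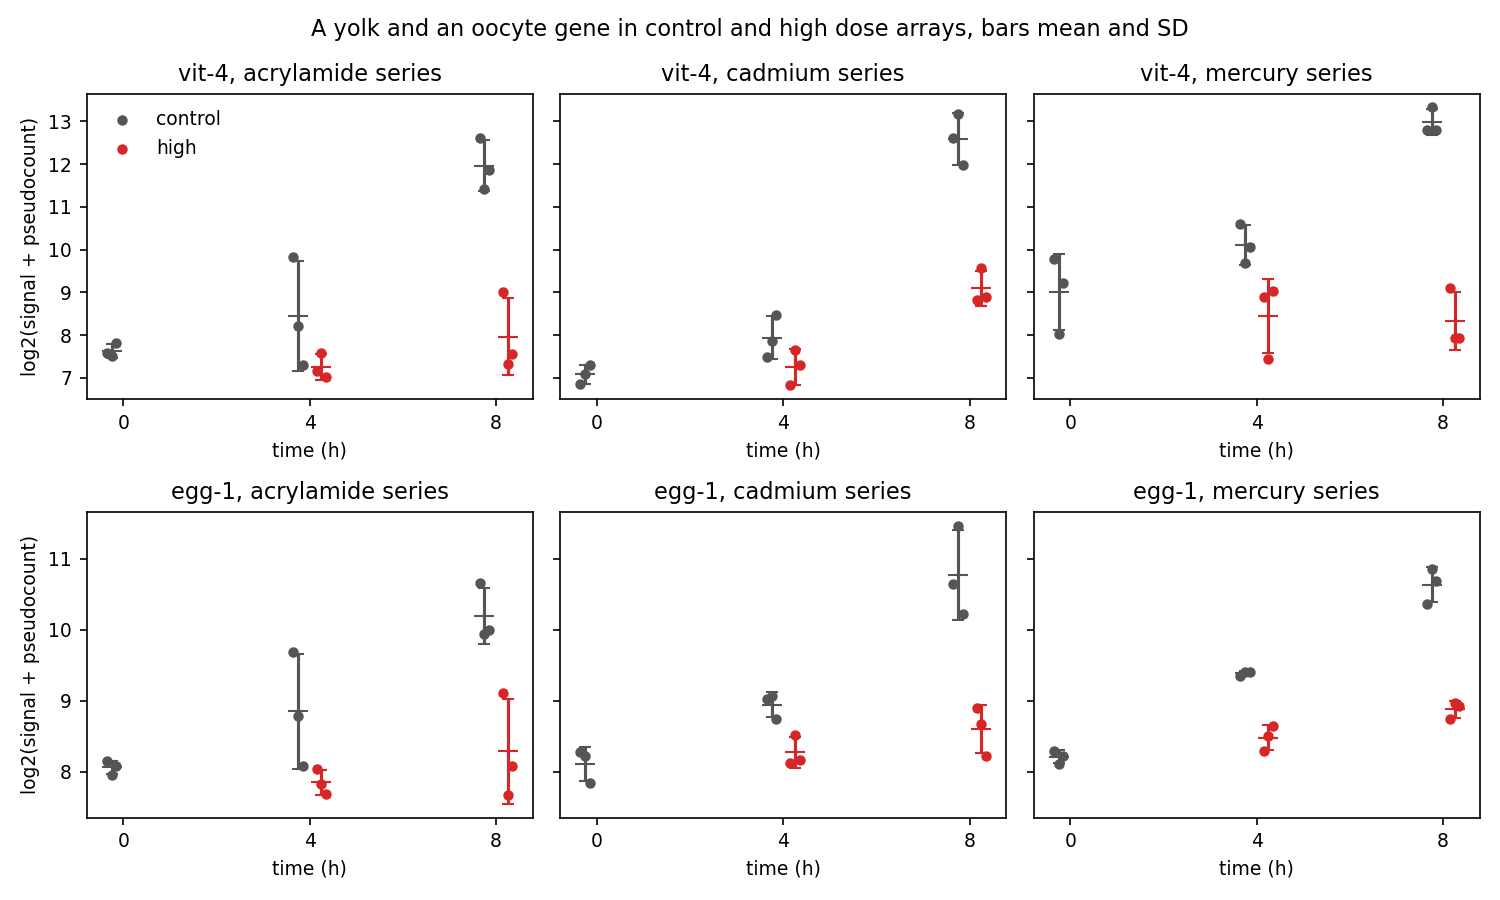
Log2 signal (vertical axis) of the yolk gene vit-4 and the egg surface gene egg-1 against time (0 h, 4 h and 8 h) in the control and high-dose arrays of each series, with a point for each array and lines through group means with bars of 1 SD. The controls rise from 0 h to 8 h and the high-dose means lie below them at 8 h in all 3 series.

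There were 7 lists that passed at none of the 6 high-dose contrasts. Their smallest adjusted p was 0.276 for the mitochondrial unfolded protein response, 0.0831 for ABC transporters, 0.202 for osmotic stress and glycerol, 0.214 for DNA damage and apoptosis, 0.0541 for lysosomal lipases and fasting response, 0.2 for pharyngeal prion-like abu proteins and 0.3 for pharyngeal muscle markers.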

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

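Tests that shuffle residuals, of single metallothionein genes and of a delay along the time course were chosen after the results were seen. The others were chosen before, 1 of them using the authors' scaling, added once the data were seen.

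High-dose effects that differed between times or between chemicals, each tested directly, stand out in 5 comparisons. The effect at 8 h differed from that at 4 h for 38 probe sets with cadmium and 126 with mercury, from 21 to 75 and from 67 to 409 under alternatives that keep the compared arrays. At 8 h the effects of cadmium and mercury differed for 599, those of cadmium and acrylamide for 432 and those of mercury and acrylamide for 595.

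Dose labels were first swapped within each time or chemical over the same 12 arrays, with 100 splits each including the real split. For the effect at 8 h less that at 4 h, 13 splits called as many as the 38 of cadmium (highest other 676) and 11 as many as the 126 of mercury (6002). For cadmium against mercury 15 splits called 599 or more (highest other 2646), for cadmium against acrylamide 15 called 432 or more (3658), and for mercury against acrylamide 18 called 595 or more (4414). By this test chance cannot be excluded for these 5. With acrylamide's 0 calls over time the test decides nothing, since all 100 splits call at least 0 (highest other 1327). Splits that call several times the real count point to a structure of the samples, here the shared dose effect: a split that keeps it at one time and reverses it at the other turns it into a difference. A further test thus removed the shared dose effect and shuffled the residuals of the 12 arrays. Among 100 shuffles, 1 called 38 for cadmium over time, the real one (highest other 1), and 1 called 126 for mercury (highest other 95). For cadmium against mercury 3 called 599 or more (highest other 635), for cadmium against acrylamide 1 called 432 (highest other 136), and for mercury against acrylamide 1 called 595 (highest other 154). By the later test chance can be excluded for these 5 if the arrays are exchangeable, which the correlation of arrays of the same replicate number puts in doubt.

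The dose trends were set against 100 splits of the arrays over the doses, and 1 split, the real one, called as many in each case. If the arrays are exchangeable, with the same doubt, chance can be excluded for acrylamide at 4 h (1209, highest other 674) and 8 h (1846, 1055), cadmium at 4 h (2045, 922) and 8 h (1533, 745), and mercury at 4 h (4156, 1403) and 8 h (5893, 3083). For a single dose against control, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real counts and the highest others at the low, mid and high dose of acrylamide were 26 and 1, 264 and 1, and 1020 and 0 at 4 h, and 54 and 0, 397 and 0, and 1450 and 0 at 8 h. For cadmium they were 99 and 0 (low) and 1150 and 0 (high) at 4 h, and 47 and 0, 326 and 0, and 1047 and 0 at 8 h. For mercury they were 428 and 0, 2595 and 1, and 3554 and 0 at 4 h, and 111 and 65, 2814 and 16, and 4932 and 6 at 8 h. For the controls at 8 h against 0 h they were 5722 and 2, 3250 and 0, and 6503 and 0 in the acrylamide, cadmium and mercury series. The cadmium mid dose at 4 h, with 2 arrays, was not split.

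Yolk and oocyte genes were lower at 8 h of the high dose in all 3 series, where the controls had raised them by a median of 2.12, 1.86 and 2.09 (each from the other series' controls; list calls lost with an estimated correlation, smallest adjusted p = 0.0812). RNA degradation (actin ratio) as sole cause was argued against with cadmium. With the ratio as covariate the 26 genes' median went from -1.68 to -1.47, and 21 fell both ways (median SE 0.35 to 0.32). Acrylamide gave -1.45 to -1.33, 15 to 9 and 0.42 to 0.47. Mercury gave -1.43 both ways, 21 to 20 and 0.22 to 0.33. Both decide nothing, as no control ratio reached the high dose's. A whole-worm delay as sole cause was placed by these genes on the controls' time course (0 h, 4 h and 8 h). It needs 0.69, 0.48 and 0.68 of probe sets that fall in the controls. Relative to all probe sets these changed by 0.09 (SD over arrays 0.15, over members 0.63), 0.01 (0.08 and 0.54) and -0.07 (0.03 and 0.82). As members went both ways (74 lower and 62 higher, 57 and 109, and 221 and 220 called), this decides nothing and the prior bound of 0.1 was too strict. Moulting genes needed 1.05, 1.29 and 1.18 and changed by 0.07, -0.03 and -0.46. These gaps lay beyond the spread over members (0.94, 0.88 and 1.39, narrowly with acrylamide) and arrays (0.45, 0.11 and 0.08). Sperm genes needed -0.6, -1.27 and -0.75 and changed by -0.25, -0.37 and -0.3 (spread of the gap 0.39, 0.5 and 0.43, not exceeded with acrylamide). A sole, partial or joint delay stays open, as does an untested change of germ line and yolk production alone. Probe sets that rise in the controls changed by -0.42, -0.47 and -0.32 (SD over arrays 0.32, 0.07 and 0.11, 113 lower and 6 higher, 168 and 8, and 315 and 42 called).

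The cadmium mid dose at 4 h called 2407 probe sets, more than the 1150 of the high dose. Without replicate 1 it called 293, so the excess may rest on that array, whose mean correlation with the others was 0.774 where those of the other cadmium arrays ran from 0.823 to 0.922. RNA of unexposed worms in that array was argued against, as its cdr-1 signal lay 6.01 log2 units above the highest control array. What set the array apart was not tested, nor was a biological explanation.

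The metallothionein genes mtl-1 and mtl-2 were lower with acrylamide while cadmium raised them. The scaling between arrays was argued against, since under 2 other scalings the change closest to 0 was -1.5. Staying at the level of 0 h while controls rose was argued against by the mean of both genes, -1.8 (SE 0.49) at 8 h of the high dose relative to 0 h, where the control mean changed by -0.18. Singly, mtl-1 lay at -2.1 (SE 0.54) at 4 h and -1.09 (SE 0.63) at 8 h and mtl-2 at -2.99 (SE 0.37) and -2.51 (SE 0.61), while the controls at 8 h changed by 0.55 and -0.91, so for mtl-1 at 8 h it stays open. An exposure effect on these transcripts stays open as a hypothesis, which rests on the same contrasts that showed the pattern.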

How the results depend on the processing

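The authors' scaling without centring, the cadmium fits without replicate 1 of the mid dose at 4 h, gene lists under quantile normalization and the actin covariate at 4 h were chosen after seeing the data, and other settings before. A count within 1.5 times its reported value is taken as the same.

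Of 33 counts, 31 were the same under the authors' scaling, 29 under quantile normalization, 32 without a pseudocount, 31 without the filter and 30 with replicate number as a block. In a fit of only the compared groups 12 of 18 were the same, and 8 of 9 in the cadmium fits without the 1 array. Fits of only the compared groups gave 0, 147 and 621 for acrylamide at 4 h (low, mid and high), 75 for mid cadmium at 4 h, 1783 for high cadmium at 8 h and 72 for low mercury at 8 h. Such fits have fewer arrays to estimate the spread. Quantile normalization gave 504 for mid cadmium at 8 h. For the effect at 8 h less that at 4 h, quantile normalization gave 8 (acrylamide), 63 (cadmium) and 272 (mercury), and the authors' scaling 3 (acrylamide) and 222 (mercury). For that effect with cadmium, no pseudocount gave 21, no filter 22, and the fit without the 1 array 75. No filter gave 67 for mercury. Apart from the smaller fits the cause was not tested.

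The labels do not pair samples by replicate number. Not every same-number pair correlated: residuals ran from -0.217 to 0.683 (acrylamide), -0.34 to 0.612 (cadmium) and -0.244 to 0.519 (mercury). Their medians were 0.131, 0.131 and 0.18. Other numbers gave -0.068, -0.082 and -0.093, pulled down as residuals cancel within groups. The main fits leave out this structure: 24 of 27, 20 of 26 and 27 of 27 arrays correlated best with their own number. A block on them gave 178 for low mercury at 8 h and, for the effect at 8 h less that at 4 h, 2 (acrylamide) and 409 (mercury). With the block cadmium and acrylamide shared 376 lower at 8 h, not 191, and cadmium and mercury 545, not 349 (odds ratio 14.1, not 24.2).

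Leaving out 1 array at a time gave, from lowest to highest, 9 to 28 for low acrylamide at 4 h and 942 to 1261 for high acrylamide at 8 h. For cadmium at 4 h the ranges were 59 to 96 (low), 293 to 7071 (mid) and 604 to 1404 (high), and at 8 h 28 to 44, 211 to 338 and 596 to 968. For mercury they were 283 to 376 (low, 4 h), 54 to 133 (low, 8 h) and 1847 to 3021 (mid, 8 h). Leaving out 1 replicate number gave, for the dose trends at 4 h and 8 h, 421 to 1316 and 635 to 2116 (acrylamide), 606 to 2618 and 741 to 920 (cadmium), and 2120 to 3803 and 3620 to 5864 (mercury). For the effect at 8 h less that at 4 h it gave 0 to 12, 2 to 11 and 0 to 127. The controls at 8 h against 0 h gave 1855 to 5878 (acrylamide) and 1949 to 3183 (cadmium). Differences between chemicals gave 1.2e+02 to 735 (cadmium and mercury), 166 to 387 (cadmium and acrylamide) and 196 to 624 (mercury and acrylamide). The other 8 counts stayed within 1.5 times. A left-out array of the cadmium mid dose at 4 h leaves 1, assumed to vary like the other groups, and fewer arrays lower the power of every such fit.

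Of the 210 list tests 95 were called. With an estimated correlation 81 of these were lost, under quantile normalization 4 were lost and 7 gained, with the authors' scaling 4 and with the block 3 were gained, and the cadmium fits without the 1 array lost 2 of 35. Over the genes named, 3052 values under alternatives kept their side of the threshold and direction, 33 lost the call, 13 gained it and 0 reversed. Those not given beside their gene are hsp-4 at 4 h of high cadmium and mtl-2 at 8 h of high mercury, called with the block (adjusted p = 0.048 and 0.04), and hsp-6 at 4 h of high cadmium without the 1 array (adjusted p = 0.042). On another probe set of the gene the calls of mtl-2 at 8 h of high acrylamide (adjusted p = 0.083, but 7.5e-05 on a further set), ttm-1 (0.078, but 0.0042 on a further set) and mlt-10 (0.17) at 4 h of high cadmium and elt-2 (0.074) and rpn-2 (0.39) at 8 h of high mercury were not made, while mtl-2 was called there (0.94 and 1.37, adjusted p = 0.0074 and 0.0035). The furthest other sets gave vit-4 at 8 h -1.88, -2.52 and -2.96 with acrylamide, cadmium and mercury instead of -4, -3.5 and -4.65, and mtl-2 with high cadmium 2.93 and 3.29 at 4 h and 8 h instead of 1.91 and 2.06. Signal over background limits dim genes: per array 38.1% to 75.94% of probe sets lay above the filter level. Simulated 2-fold changes were recovered in 36% to 75% at the high dose but 5% to 40% for the effect at 8 h less that at 4 h.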

Other observations

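The tests of this part were chosen before the results were seen, and the genes named after. At 8 h of the high dose, further contrasts of single genes differed between the chemicals. Mercury gave lower transcripts than acrylamide of the invertebrate lysozyme genes ilys-2 (log2 difference -4.45, SE 0.51, adjusted p = 2.4e-09) and ilys-3 (-3.68, SE 0.38, adjusted p = 1.3e-10). The choline kinase gene ckb-2 was higher with mercury (3.93, SE 0.40, adjusted p = 6.8e-11). Cadmium gave lower transferase genes than acrylamide, namely gst-31 (-4.69, SE 0.38, adjusted p = 1.8e-14) and gst-40 (-3.51, SE 0.30, adjusted p = 2e-13).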
